A study of Mus musculus with 8 samples.

How the data were processed

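Polyadenylated RNA from whole mouse uteri collected at gestation day 3.5 was measured by RNA-seq in 8 libraries, 4 from Grb2 f/f females (called control) and 4 from Pgr cre/+ Grb2 f/f females (called Grb2-deleted). Per the labels' protocols, RNA came from uteri of intact adult females and libraries were made with a kit that selects mRNA, then sequenced as paired ends. The group and the replicate number of each library were taken from its title.

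The deposited values were whole-number counts per Ensembl gene, 1 column per library, not normalized and not pooled. Per the submitters' processing notes, cutadapt 1.18, Trim Galore 0.6.4, FastQC 0.11.9 and STAR 2.7.3a were used with the genome build GRCm38. The setting of the counting step, its strand and the annotation release were not given in the sources used here. Reads from overlapping genes on opposite strands therefore may not be told apart, and their values are uncertain. Of the genes named by rule, these are Bhlhe40, Cftr, Des, Egfl7, Eomes, Fgf10, Fst, Gli1, Grid2ip, Hand2, Hhip, Hoxa11, Krt7, Mpo, Muc4, Ncam1, Ncoa3, Notch3, Oasl1, Pdgfa, Reln, Tgfa and Wnt7b, while Pcp4 and Egfl7 share exon positions with a gene on the same strand. Members of near-identical gene families (Sprr2, immunoglobulin, alpha-globin and Ly6 genes) can share reads and are uncertain in the same way.

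Gene symbols and coordinates came from the GENCODE annotation of GRCm38. Of 45706 gene identifiers, 45143 (98.77%) matched, and these held 99.94% of the counts. Every column belonged to 1 of the 8 libraries, and no row was a total or unassigned class. Of all genes, 16012 had no count in any library. Library totals ranged from 37932554 to 41659251 counts. A floor of 3 counts in 1 library corresponded to 0.072 to 0.0791 CPM, the unit of counts scaled to a common library total. No pair of libraries matched within sampling noise: the lowest chi-square per gene between any pair was 24.68, over genes with at least 10 counts.

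Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, library sizes were scaled by trimmed mean of M values (TMM), and 17836 genes were tested with the robust quasi-likelihood F test of Grb2-deleted against control. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. The residual degrees of freedom were 6 and the median biological coefficient of variation was 16.8%. Standard errors (SE) of log2 fold changes are approximate, taken as the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, as mean ± SD over 4 libraries. Where a group held 1 to 3 counts of a gene in total, the ratio is given with an exact 95% counting interval. Where a group held none, the fold is a lower bound against 3 counts over the group. Such intervals and floors cover counting error only. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

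The 33 gene lists (15 pathway or function lists and 18 cell type lists) and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists. They were repeated with an estimated correlation and with fry. The form with an estimated correlation gave larger p-values even where that correlation was low, so a call lost with it need not reflect correlated genes. The ovary list had 4 tested members and the preimplantation embryo list 0, so neither was tested. Named genes were Grb2 and Pgr, the 12 largest rises and 12 largest falls, and up to 4 members of each list. The rises and falls were taken among called genes with a mean of at least 1 CPM, non-overlapping groups and an informative symbol. The list members were those with the smallest adjusted p, or where none passed up to 2 with the highest mean CPM. Other list members named in the text were chosen after their values were seen.

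The edgeR and camera steps were tested on simulated data for the Grb2-deleted against control comparison over 17285 genes. The simulated means and spread came from the control libraries alone, and the library sizes from all 8 libraries. Of genes changed by an absolute log2 fold change of 0.5, 46.7% were recovered. For 1 and 2 the shares were 78.7% and 100%. The 14 false calls made up 8.86% of the calls. The changed list was called, and 0 of the unrelated lists were.

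Alternatives were other scalings (RLE, upper quartile, library size only), no filter and a stricter filter (at least 1 CPM in at least 4 libraries), the replicate number as a block, the smooth muscle list mean as a covariate, each library left out in turn, non-robust moderation, DESeq2 1.42.0, limma-voom, an estimated inter-gene correlation and fry. Analysis of single exons of Grb2, which the gene-level counts do not separate, was not done here.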

Results

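Uterine transcript levels were compared between 4 control libraries and 4 libraries from females in which Cre, expressed from the Pgr locus, deletes floxed Grb2. GRB2 is an adaptor protein that links activated receptor tyrosine kinases to RAS signalling. The controls carried the floxed alleles without Cre, so the genotypes also differed in the presence of Cre at 1 copy of Pgr. All uteri were taken at gestation day 3.5, shortly before the mouse uterus accepts an embryo. The question was how uterine gene expression differs once endometrial Grb2 is deleted. Totals were 41212700, 41659251, 39953431 and 40738865 counts in control replicates 1 to 4, and 41404565, 39991511, 37932554 and 41213470 counts in Grb2-deleted replicates 1 to 4.

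Grb2 itself (chromosome 11, 115644045 to 115708597, GRCm38, minus strand, protein-coding) fell in the Grb2-deleted libraries, from 120.2 ± 4.42 to 95.4 ± 9.83 CPM (SD, n = 4 each). Its log2 fold change was -0.33 (SE 0.08, adjusted p = 0.0114, edgeR quasi-likelihood test). All 4 deleted libraries (81.7, 95.02, 101.9 and 103.1 CPM) lay below all 4 controls (113.7, 122.8, 121.4 and 123.1 CPM). With the smooth muscle list mean as a covariate the log2 fold change was -0.45 with a larger SE of 0.19, and was not called (adjusted p = 0.18). The counts cover the whole gene in whole uterus, including cells without Cre and exons outside any deleted part. Pgr, the progesterone receptor gene at which the Cre is inserted (chromosome 9, 8899833 to 8968611, plus strand), rose from 248 ± 12.5 to 454 ± 37.7 CPM. The log2 fold change of Pgr was 0.87 (SE 0.08, adjusted p = 9.07e-05). The counts do not separate transcripts of the Pgr copy with Cre from those of the intact copy.

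The genotypes differed in 6421 of 17836 tested genes (36%), with 3174 risen and 3247 fallen in Grb2-deleted uterus. At least 2-fold changes numbered 1354 up and 951 down. With library size alone in place of TMM scaling, 63.5% instead of 49.4% of the calls were rises. That scaling moved the median log2 fold change of all genes to 0.10 from 0.01. For 37.9% of tested genes the groups did not overlap, against 2.86% by chance. The first principal component held 62.6% of the variance and separated the groups. On the second (15%), Grb2-deleted replicate 1 scored 65.7 and the other deleted libraries -24.0 to -29.8. Without that library 7138 genes were called. With the smooth muscle list mean as a covariate, which itself followed genotype, 1100 genes were called, 722 of them risen.

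**Figure D1:**
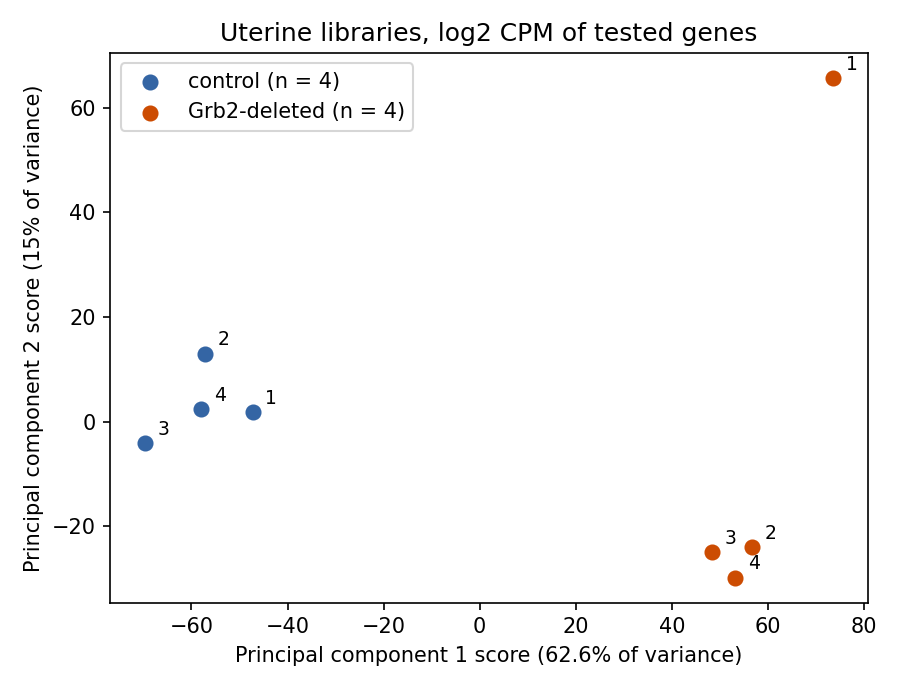
Scores of the 8 libraries on the first and second principal components of log2 CPM over tested genes (unitless; percent of variance on each axis, numbers give the replicate). Controls lie at -47.2 to -69.7 and Grb2-deleted libraries at 48.4 to 73.6 on the first component, and Grb2-deleted replicate 1 stands apart at 65.7 on the second.

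Among the largest rises were genes almost without counts in control uterus. Wif1, a secreted WNT inhibitor (chromosome 10, 121033960 to 121100650), had 1 count over the 4 controls and 5601 over the 4 deleted libraries, a ratio of 5360 (95% counting interval 961 to 212000, adjusted p = 7.82e-06). The single control count was in replicate 1, and without that library the fitted log2 fold change was 13.43 instead of 11.81. Foxi3, a forkhead transcription factor gene, had 1 against 625 counts (ratio 598, interval 107 to 23700), and its single control count was also in replicate 1 (fitted log2 fold change 10.26 without that library, 8.65 with it). Il1f6, which encodes interleukin 36 alpha, had 2 against 1299 counts (ratio 621, interval 172 to 5140); its fitted log2 fold change was 8.14 without Grb2-deleted replicate 4 and 8.95 with it. Gabrp, a GABA receptor subunit gene, rose 274-fold, from 0.699 ± 0.520 to 191 ± 43.2 CPM (adjusted p = 1.35e-05). Fat2, Upk3bl, G6pc2 and Serpinb7 rose 133-, 118-, 113- and 109-fold from means under 0.1 CPM. They had only 7, 6, 4 and 4 counts over the 4 controls, so these folds are imprecise. Without control replicate 2 the log2 fold change of Fat2 was 7.68 instead of 6.95. A further 4 of the 12 rises owed much of their size to Grb2-deleted replicate 1. Clca1, a secreted goblet-cell protein gene, reached 725 CPM there and 66.5 to 126 CPM in the other deleted libraries, and its log2 fold change was 8.27 with and 6.77 without it. Erbb4, a receptor of the epidermal growth factor family, had 2 against 1146 counts (ratio 548, interval 151 to 4530) and its fitted log2 fold change moved from 8.77 to 6.97. Sox1ot, a non-coding transcript, moved from 8.15 to 4.54, and Chil1 from 7.45 to 4.07. Without control replicate 1, Sox1ot was at 8.93. All 4 stayed past the threshold without Grb2-deleted replicate 1, while Sox1ot and Chil1 missed it with limma-voom (adjusted p = 0.0536 and 0.0783) and with no filter on low counts (adjusted p = 0.0552 and 0.0519).

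Spink1, a gland-secreted protease inhibitor gene (chromosome 18, 43728082 to 43737557), had the largest fitted fall of the genes named by rule, with 7753 counts over the controls and 2 over the deleted libraries (ratio 4050, counting interval 1120 to 33500, adjusted p = 1.56e-06). Adarb2 had 479 counts over the controls and 0 over the deleted libraries, at least 167-fold lower, and has no finite fold to rank. Angptl7, an angiopoietin-like secreted protein gene, fell 199-fold, from 213 ± 62.3 to 1.07 ± 0.194 CPM (adjusted p = 3.04e-06). Areg, the epidermal growth factor receptor ligand amphiregulin and a progesterone-responsive gene, fell 137-fold, from 8.47 ± 2.44 to 0.0617 ± 0.0496 CPM. Rims3 fell 48.1-fold from 120.4 ± 11.1 CPM. The dopamine receptor gene Drd4, Cyp3a59, the tachykinin gene Tac2, the transthyretin gene Ttr, Abcb5, the tryptophan-degrading enzyme gene Tdo2 and Grid2ip fell 48.2- to 234-fold. Drd4 was at 0.0312 ± 0.0379 CPM in deleted libraries, so its fold is imprecise. Grid2ip shares exon positions with a gene on the other strand and is uncertain. The log2 fold changes of Drd4 and Abcb5 were -8.60 and -6.39 without Grb2-deleted replicate 3, against -7.77 and -5.77 with it. Tdo2 was at -4.98 without control replicate 3, against -5.65.

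**Figure D2:**
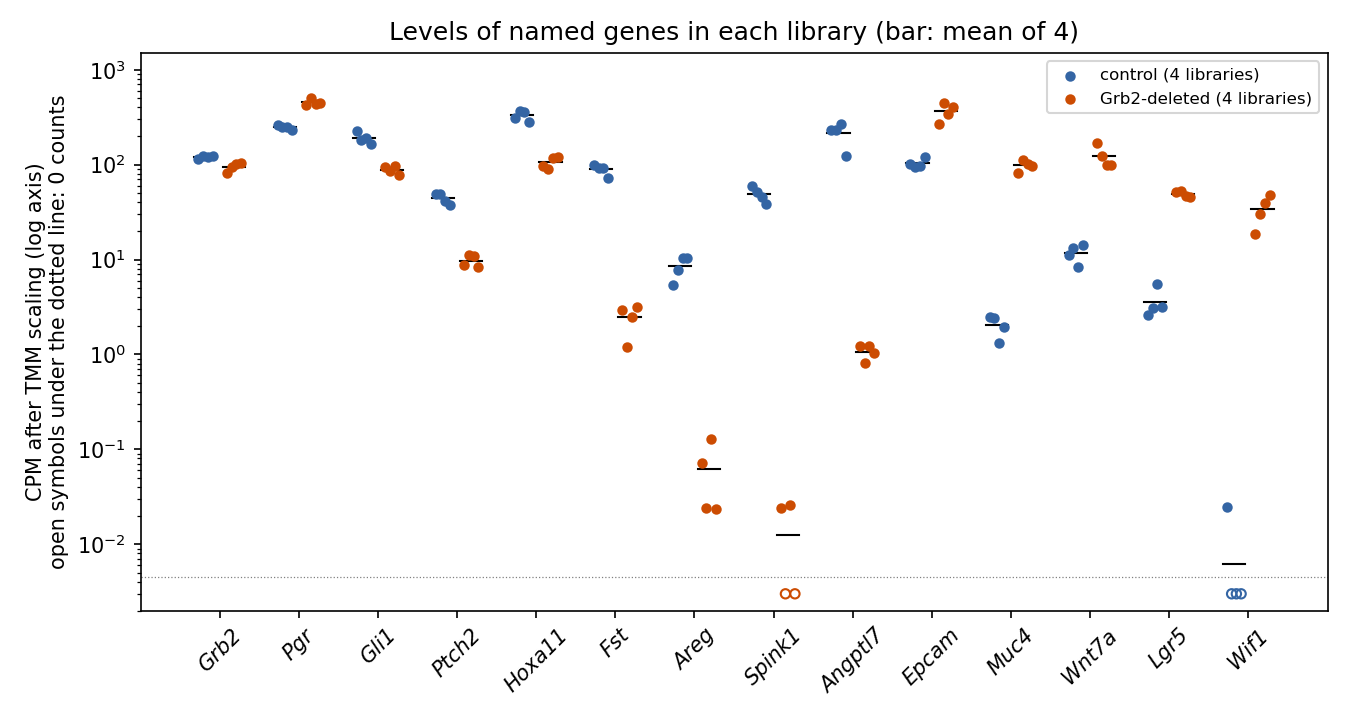
CPM after TMM scaling on a log axis for 14 named genes; each point is 1 library, black bars are means of 4, and open symbols under the dotted line are libraries with 0 counts. Grb2-deleted and control points do not overlap for any gene shown, from 95.4 against 120.2 CPM on average for Grb2 to 5601 against 1 counts for Wif1. Apart from Grb2 and Pgr, the genes come from a rule that selects non-overlapping groups or the smallest adjusted p. Over all tested genes the groups did not overlap for 37.9%.

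Genes of the hedgehog pathway, through which uterine epithelium signals to stroma, fell as a group. Of 13 members 10 fell and 0 rose, both over all genes and adjusted over the list alone. The median log2 fold change was -0.85 (camera adjusted p = 2.74e-08; adjusted p = 0.0925 with an estimated correlation). The receptor and target gene Ptch2 fell from 44.4 ± 5.69 to 9.73 ± 1.45 CPM (log2 fold change -2.19, SE 0.14, adjusted p = 1.95e-05). The hedgehog-binding Hhip fell by 1.81, and the transcription factor genes Gli1 and Hand2 fell by 1.11 and 0.82 on the log2 scale. Gli1, Hhip and Hand2 have overlapping genes on the other strand. Ihh, the ligand gene, was at 48.7 ± 5.94 and 50.3 ± 24.1 CPM (log2 fold change 0.05, SE 0.32, adjusted p = 0.925). Endometrial stroma markers were lower in the same libraries (median -1.16).

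Progesterone-induced genes were also mostly lower: 16 of 25 fell and 3 rose (16 and 4 adjusted over the list alone), with a median log2 fold change of -1.09 (camera adjusted p = 5.68e-11; adjusted p = 0.0925 with an estimated correlation). Besides Areg, the activin-binding follistatin gene Fst fell from 89.1 ± 12.1 to 2.45 ± 0.889 CPM (log2 fold change -5.18, SE 0.28). Calca, which encodes calcitonin peptides, fell 32.8-fold to 0.152 ± 0.0592 CPM. Hoxa11, a homeobox gene of the uterine stroma with an antisense partner, fell from 330 ± 42.4 to 107 ± 14.9 CPM. The endocytic receptor gene Lrp2 fell from 654 ± 156 to 25.9 ± 17.9 CPM. The 3 members that rose were Bmp2, Sox17 and Cyp26a1 (log2 fold changes 0.45, 0.74 and 2.03). Stroma markers (median -1.16) and gland epithelium markers (median -4.18) were lower in the same libraries, and the stroma list shares Hoxa10, Hoxa11 and Hand2 with this one. The hedgehog list shares Ihh, Ptch1, Gli1, Nr2f2 and Hand2 with the progesterone-induced list, so their falls are not independent. Without Grb2-deleted replicate 1, 18 fell and 2 rose.

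Oestrogen-induced epithelial genes rose in the opposite direction: 20 of 23 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 2.86 (camera adjusted p = 7.55e-20). This was the only list of 31 called with an estimated correlation (adjusted p = 0.00198). Its estimated correlation was 0.006, below the preset 0.01, yet its unadjusted camera p went from 2.43e-21 to 6.39e-05. The form with an estimated correlation was thus the weaker test here for a reason other than correlated genes. The mucin gene Muc4 rose 48.2-fold, from 2.04 ± 0.533 to 98.2 ± 12.5 CPM (adjusted p = 1.91e-06), and shares exon positions with a gene on the other strand. The gap junction gene Gjb2 rose 35.6-fold, the peptidylarginine deiminase gene Padi4 11.0-fold and the WNT ligand gene Wnt7a 10.4-fold. The lactoferrin gene Ltf rose from 22.1 ± 21.2 to 714 ± 533 CPM (log2 fold change 5.02, SE 0.82, and 5.93 without control replicate 4). Olfm1 was the member that fell, from 92.7 ± 20.6 to 49.2 ± 4.52 CPM. Epithelium markers rose in the same libraries. The oestrogen-induced epithelial list includes several near-identical Sprr2 genes that can share reads. Its member counts and its list test treat them as separate genes. Without Grb2-deleted replicate 1, C3 and Padi1 had log2 fold changes of 1.36 and 2.27 instead of 1.98 and 2.86. Sprr2b and Krt15 were at 7.24 and 4.79 without control replicate 2, against 5.95 and 3.17.

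The list of oestrogen-induced growth and proliferation genes was mixed, with 9 of 18 risen and 4 fallen (9 and 5 adjusted over the list alone), and was not called (median 0.52, camera adjusted p = 0.169). Igf1, insulin-like growth factor 1, fell from 794 ± 135 to 205 ± 39.9 CPM (log2 fold change -1.95, SE 0.17, adjusted p = 9.64e-05), and Myc from 143.9 ± 9.44 to 89.3 ± 8.28 CPM. Bhlhe40 and Ncam1 rose 1.98- and 3.53-fold. Bhlhe40 and Ncam1 have overlapping genes on the other strand. Proliferation genes had 2 of 30 members risen and 0 fallen over all genes, and 0 and 0 adjusted over the list alone (median 0.21, camera adjusted p = 0.711). The 2 that rose were the replication licensing genes Mcm2 and Mcm6 (1.40- and 1.41-fold). Mcm2 missed the threshold without control replicate 2 (adjusted p = 0.0544). The mean log2 CPM of the proliferation list was 3.87 in Grb2-deleted replicate 1, 5.50 to 6.03 in the other deleted libraries and 5.01 to 5.63 in controls. Without that library 12 members rose (camera adjusted p = 0.00555), and the oestrogen growth list was called with 11 risen and 3 fallen (camera adjusted p = 0.0142). With an estimated correlation neither was called (adjusted p = 0.618 and 0.169 without that library, 0.972 and 0.331 with all 8). Without control replicate 2 or 3 the oestrogen growth list had 8 risen and 2 fallen, and without control replicate 2 the proliferation list had 1 risen.

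Gland and implantation genes went both ways: 8 of 22 rose and 7 fell (9 and 9 adjusted over the list alone; median -0.01, camera adjusted p = 0.142). Besides Spink1, Areg and Ttr, the gland protein gene Wfdc3 fell from 11.8 ± 2.76 to 0.650 ± 0.133 CPM (log2 fold change -4.18, SE 0.24). Lif, the cytokine that glands secrete before implantation, fell from 17.2 ± 9.09 to 3.03 ± 0.919 CPM (log2 fold change -2.51, SE 0.38, adjusted p = 0.00111). Its receptor gene Lifr rose (log2 fold change 1.98), as did the homeobox genes Msx1 and Msx2 (0.96 and 3.08). In the narrower gland epithelium list 4 of 7 members fell and 0 rose (5 and 0 adjusted over the list alone). Its median was -4.18 (camera adjusted p = 7.17e-10; adjusted p = 0.0925 with an estimated correlation). The 4 were Spink1, Ttr, Wfdc3 and the protease gene Prss29, which had 216 counts in controls and 2 in deleted libraries (ratio 113, counting interval 30.9 to 938). Both Prss29 counts were in Grb2-deleted replicate 1, and its fitted log2 fold change was -8.78 without and -6.49 with that library. The list median is the value of Wfdc3 and does not depend on the fitted values of Spink1 and Prss29. The gland transcription factor gene Foxa2 was at 15.5 ± 4.29 and 8.88 ± 3.29 CPM (adjusted p = 0.0644), and Cxcl15 at 44.0 ± 13.0 and 49.5 ± 26.6 CPM (adjusted p = 0.772).

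ERBB receptors and their ligands had 8 of 13 members risen and 3 fallen (8 and 3 adjusted over the list alone; median 1.17, camera adjusted p = 0.0803). Without Grb2-deleted replicate 1 or 3 the list was called (adjusted p = 0.0398 and 0.0262), but not with an estimated correlation (adjusted p = 0.252 and 0.181). The ligand genes Tgfa, Hbegf and Btc rose 3.31-, 2.47- and 4.33-fold, while Areg, Egfr and the feedback inhibitor gene Errfi1 fell (log2 fold changes -7.05, -0.88 and -1.33). Tgfa has an overlapping gene on the other strand. Nrg1 had a log2 fold change of 3.34, and 3.96 without control replicate 1. Of the GRB2 and RAS-MAPK components, 6 of 24 fell and 2 rose, also adjusted over the list alone (median -0.08, camera adjusted p = 0.519). Apart from Grb2, the adaptor genes Frs2, Shc1 and Gab2 fell by 0.32, 0.33 and 0.52 on the log2 scale. Gab2 missed the threshold without control replicate 3 (adjusted p = 0.0541). The split of this list varied with single libraries: 4 rose and 6 fell without Grb2-deleted replicate 1, where Nras and Grap2 joined (log2 fold changes 0.39 and 0.78, adjusted p = 0.00134 and 0.0453). Without Grb2-deleted replicate 2 or any 1 control it was 0 or 1 risen and 3 to 5 fallen. ERK-induced feedback genes had 3 of 19 members risen and 4 fallen (5 and 5 adjusted over the list alone). Their median was 0.06 and their mean -0.04, and the test pointed down (camera adjusted p = 0.945). Without control replicate 2 or Grb2-deleted replicate 3 only 2 fell, with 3 and 4 risen. Spred2 and Dusp4 rose 1.95- and 2.58-fold and Spry4 fell 2.30-fold. Fibroblast and insulin-like growth factors had 7 of 19 risen and 4 fallen, also adjusted over the list alone (median 0.12, camera adjusted p = 0.177). Met, the receptor of hepatocyte growth factor, rose 2.66-fold, and Fgf10 and Pdgfa, both with overlapping genes on the other strand, rose 2.84- and 2.01-fold.

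WNT signalling genes rose on balance: 13 of 24 rose and 3 fell, also adjusted over the list alone (median 0.28, camera adjusted p = 0.000117; adjusted p = 0.0925 with an estimated correlation). Besides Wif1 and Wnt7a, Lgr5, a receptor for R-spondins, rose from 3.59 ± 1.32 to 48.9 ± 3.92 CPM (log2 fold change 3.77, SE 0.23). Wnt7b, which has an overlapping gene, rose from 0.595 ± 0.290 to 13.3 ± 3.89 CPM. The 3 that fell were Wnt6, Lef1 and Sfrp4 (log2 fold changes -1.18, -1.35 and -2.15). Epithelium markers rose and stroma markers fell in the same libraries (medians 1.22 and -1.16). Early decidual and stromal differentiation genes had 6 of 18 risen and 9 fallen, also adjusted over the list alone. Their median was -0.39 and their mean 0.04, and the test pointed down (camera adjusted p = 0.0757). Without control replicate 3, Grb2-deleted replicate 3 or Grb2-deleted replicate 4 the list passed (adjusted p = 0.0469, 0.0463 and 0.0498), but not with an estimated correlation (adjusted p = 0.466, 0.386 and 0.499). Without control replicate 2 it had 3 risen and 9 fallen. Wnt4 rose from 6.46 ± 1.93 to 45.6 ± 12.7 CPM, and Hoxa10 fell from 414 ± 28.8 to 195 ± 32.5 CPM. Steroid receptors and cofactors had 11 of 16 risen and 3 fallen, also adjusted over the list alone (median 0.46, camera adjusted p = 0.0108; adjusted p = 0.203 with an estimated correlation). The oestrogen receptor gene Esr1 rose from 499.6 ± 48.2 to 722 ± 114 CPM (log2 fold change 0.53, SE 0.12), and Pgrmc1 and Ncoa3 rose 1.48- and 1.45-fold. Ncoa3 has an overlapping gene. The progesterone-responsive cochaperone gene Fkbp5 fell from 72.9 ± 13.5 to 17.6 ± 7.75 CPM. Esr2 was at 2.34 without Grb2-deleted replicate 2, against 3.06. The steroid receptor list lost its call with the smooth muscle covariate (adjusted p = 0.0607).

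Interferon-stimulated genes rose together, with 18 of 22 risen and 0 fallen, also adjusted over the list alone. The median was 1.31 (camera adjusted p = 4.25e-13; adjusted p = 0.193 with an estimated correlation). The antiviral genes Mx1, Mx2, Oasl1 and Ifit1 rose 6.05-, 3.27-, 3.79- and 3.41-fold. Ion and water transport genes had 4 of 18 risen and 4 fallen (5 and 4 adjusted over the list alone; median 0.16, camera adjusted p = 0.402). The chloride channel gene Cftr rose from 3.13 ± 1.17 to 65.2 ± 13.6 CPM (log2 fold change 4.38, SE 0.29) and the carbonic anhydrase gene Car2 from 116 ± 18.7 to 341.8 ± 100.7 CPM. The sodium channel subunit gene Scnn1b and the anion exchanger gene Slc26a6 fell by 1.02 and 0.75 on the log2 scale.

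Cell type markers moved with genotype. Of the epithelium markers 14 of 15 rose and 0 fell (14 and 1 adjusted over the list alone), with a median of 1.22 (camera adjusted p = 2.43e-16; adjusted p = 0.0925 with an estimated correlation). Epcam rose from 103 ± 12.3 to 366 ± 81.5 CPM, Krt7 4.38-fold, St14 3.66-fold and Tacstd2 34.5-fold. Endometrial stroma markers had 10 of 15 fallen and 1 risen (10 and 2 adjusted over the list alone; median -1.16, camera adjusted p = 1.04e-07; adjusted p = 0.193 with an estimated correlation). The intermediate filament gene Vim fell from 1187 ± 136 to 482 ± 59.3 CPM and the collagen gene Col6a3 from 1092 ± 235 to 320 ± 68.5 CPM, while Mfap4, an extracellular microfibril gene, rose from 135 ± 37.4 to 332 ± 143 CPM. Smooth muscle markers had 12 of 15 fallen and 0 risen (13 and 0 adjusted over the list alone; median -1.08, camera adjusted p = 2.07e-07; adjusted p = 0.331 with an estimated correlation). Actg2 and Des fell from 1115 ± 389 to 224 ± 46.8 CPM and from 1089 ± 227 to 344 ± 86.6 CPM, and Synpo2 and Pcp4 fell 2.35- and 2.46-fold. Pcp4 shares exon positions with another gene.

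Among vascular markers, endothelium genes had 8 of 12 fallen and 0 risen (8 and 1 adjusted over the list alone; median -0.35, camera adjusted p = 0.00263; adjusted p = 0.203 with an estimated correlation), with Cdh5, Egfl7, Esam and Kdr lower by 0.95, 0.92, 0.68 and 0.35 in log2. Egfl7 has an overlapping gene. Pericyte markers had 4 of 7 fallen and 0 risen, also adjusted over the list alone (median -0.51, camera adjusted p = 0.0122; adjusted p = 0.203 with an estimated correlation). They were Cspg4, Rgs5, Notch3 and Pdgfrb (log2 fold changes -1.49, -1.49, -0.75 and -0.48). Pdgfrb missed the threshold in each of 7 fits that left out 1 library (adjusted p = 0.0519 to 0.11). It also missed the threshold with library size only (adjusted p = 0.0787) and with no filter on low counts (adjusted p = 0.0536). Lymphatic endothelium had 4 of 6 risen and 0 fallen, also adjusted over the list alone (median 0.34, camera adjusted p = 0.0757). Mmrn1, Reln, Ccl21a and Flt4 rose 1.78-, 1.96-, 1.28- and 1.25-fold. The list passed without Grb2-deleted replicate 2 (adjusted p = 0.00312), but not with an estimated correlation (adjusted p = 0.212).

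Of T and NK cell markers, 9 of 15 fell and 0 rose (9 and 1 adjusted over the list alone; median -1.24, camera adjusted p = 0.000456; adjusted p = 0.331 with an estimated correlation). All 4 named members are cytotoxic NK or T cell genes: Gzmb fell from 27.2 ± 6.46 to 2.74 ± 1.07 CPM, Prf1 from 9.10 ± 2.53 to 2.12 ± 0.129, Gzma from 11.1 ± 3.27 to 2.91 ± 0.346 and Eomes from 10.2 ± 1.31 to 3.92 ± 0.748. The T cell receptor component gene Cd3e was at 2.73 ± 0.497 and 5.18 ± 3.03 CPM (adjusted p = 0.226). Without Grb2-deleted replicate 1, whose list mean was 1.15 in log2 CPM against 2.18 to 2.37 in the other deleted libraries, 9 fell and 4 rose. Those 4 were the T cell genes Cd3d, Cd3e, Cd3g and Cd4 (log2 fold changes 1.61, 1.28, 1.2 and 1.34). Macrophage and dendritic cell markers had 1 of 13 risen (Cd163, log2 fold change 1.35) and 1 fallen (Mrc1, -0.96), and 0 and 0 adjusted over the list alone (median -0.14, camera adjusted p = 0.742). Cd163 missed the threshold in each of 6 fits that left out 1 library (adjusted p = 0.0893 to 0.114) and with limma-voom (adjusted p = 0.124). It also missed the threshold with no filter on low counts (adjusted p = 0.0575). Without Grb2-deleted replicate 1 the 2 risen were Cd68 and Mafb (log2 fold changes 0.76 and 0.57, adjusted p = 0.0245 and 0.049), and without any 1 of 5 other libraries 0 rose. Neutrophil markers had 1 of 7 risen (Ly6g, of a family of similar genes) and 1 fallen (Mpo), also adjusted over the list alone (median 0.48, camera adjusted p = 0.742). The split was 4 risen and 1 fallen without Grb2-deleted replicate 1: S100a9, Cxcr2 and Csf3r joined Ly6g (log2 fold changes 1.02, 1.48 and 0.79, adjusted p = 0.0271, 0.0262 and 0.00451). B and plasma cell markers had 0 of 8 called in edgeR, DESeq2 and limma-voom and 0 at an unadjusted p under 0.05, and 0 in edgeR adjusted over the list alone (median -0.31, camera adjusted p = 0.727). Cd19 rose without Grb2-deleted replicate 1 (log2 fold change 1.09, adjusted p = 0.0403). The immunoglobulin gene Igha was at 2158 ± 899 and 1285 ± 877 CPM and Igkc at 1160 ± 451 and 756 ± 536 CPM, with similar family members that can share reads. All of these leukocyte lists were lowest in Grb2-deleted replicate 1.

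Markers of tissues next to the uterus varied within groups, and some also differed between them. The mean log2 CPM of the oviduct and ciliated cell list was 2.68 to 3.52 in controls and 1.97 to 2.51 in deleted libraries. For the stratified cervicovaginal list it was -0.79 to -0.07 in controls and 0.14 to 1.12 in deleted libraries. Mesothelium markers had 1 of 6 risen (Gpm6a, log2 fold change 0.90) and 1 fallen (Wt1, -0.40), also adjusted over the list alone (median 0.27, camera adjusted p = 0.945). Gpm6a missed the threshold in 6 fits that left out 1 library (adjusted p = 0.0582 to 0.101), and Wt1 in 2 (adjusted p = 0.0523 and 0.0552). Adipocyte markers depended on the tool. In edgeR 0 of 9 were called over all genes and adjusted over the list alone, and 2 had an unadjusted p under 0.05 (median 2.14, camera adjusted p = 0.0999), while DESeq2 called 1 (Lpl, adjusted p = 0.0177) and limma-voom 6, among them Cfd (adjusted p = 0.0371). Lpl was at 74.3 ± 13.6 and 132 ± 60.8 CPM and Cfd at 11.3 ± 21.5 and 49.8 ± 34.1 CPM. Lpl passed in edgeR with library size only (adjusted p = 0.0445) and without Grb2-deleted replicate 1 or 2 (adjusted p = 0.0242 and 0.0342), and Cfd without control replicate 1 (log2 fold change 6.52, adjusted p = 0.00468). The list mean was 3.78 in log2 CPM in control replicate 1 and -1.90 to -0.30 in the other controls, against 2.48 to 4.83 in deleted libraries. Without control replicate 1 the list was called, with 7 members risen and a median of 6.52 (adjusted p = 0.000179; adjusted p = 0.334 with an estimated correlation). Oviduct and ciliated cell markers had 1 of 6 risen (Foxj1) and 4 fallen (Dnah5, Rsph1, Tppp3 and Ovgp1), also adjusted over the list alone (median -0.63, camera adjusted p = 0.286). Ovgp1 was no longer past the threshold without control replicate 4 (log2 fold change -1.24 instead of -2.65, adjusted p = 0.115), nor without Grb2-deleted replicate 1, 2 or 4 (adjusted p = 0.102, 0.0901 and 0.0857). Tppp3 missed it in 4 fits that left out 1 library (adjusted p = 0.0647 to 0.0696) and Rsph1 in 3 (adjusted p = 0.0569 to 0.0606). The log2 fold changes of Foxj1 and Dnah5 were 1.56 without Grb2-deleted replicate 4 and -2.86 without Grb2-deleted replicate 1, against 2.24 and -2. Stratified cervicovaginal markers had 2 of 5 risen and 0 fallen, also adjusted over the list alone (median 0.04, camera adjusted p = 0.281). They were the basal cell transcription factor gene Trp63 and the keratin gene Krt13 (2.84- and 7.90-fold). Ovary markers had 0 of 4 tested members called in edgeR, DESeq2 and limma-voom (0, 1 and 1 at an unadjusted p under 0.05; median -0.27), with Star at 4.39 ± 0.863 and 4.78 ± 2.20 CPM and Inha at 4.12 ± 0.590 and 3.20 ± 0.328 CPM. Erythrocyte markers had 0 of 5 called in edgeR, DESeq2 and limma-voom and 0 at an unadjusted p under 0.05, and 0 in edgeR adjusted over the list alone (median 0.23, camera adjusted p = 0.945), with Hbb-bs at 27.0 ± 14.8 and 31.7 ± 15.8 CPM and Hba-a1, a near-identical copy of Hba-a2, at 4.33 ± 2.33 and 4.71 ± 2.63 CPM. None of the 8 preimplantation embryo markers passed the filter on low counts.

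**Figure D3:**
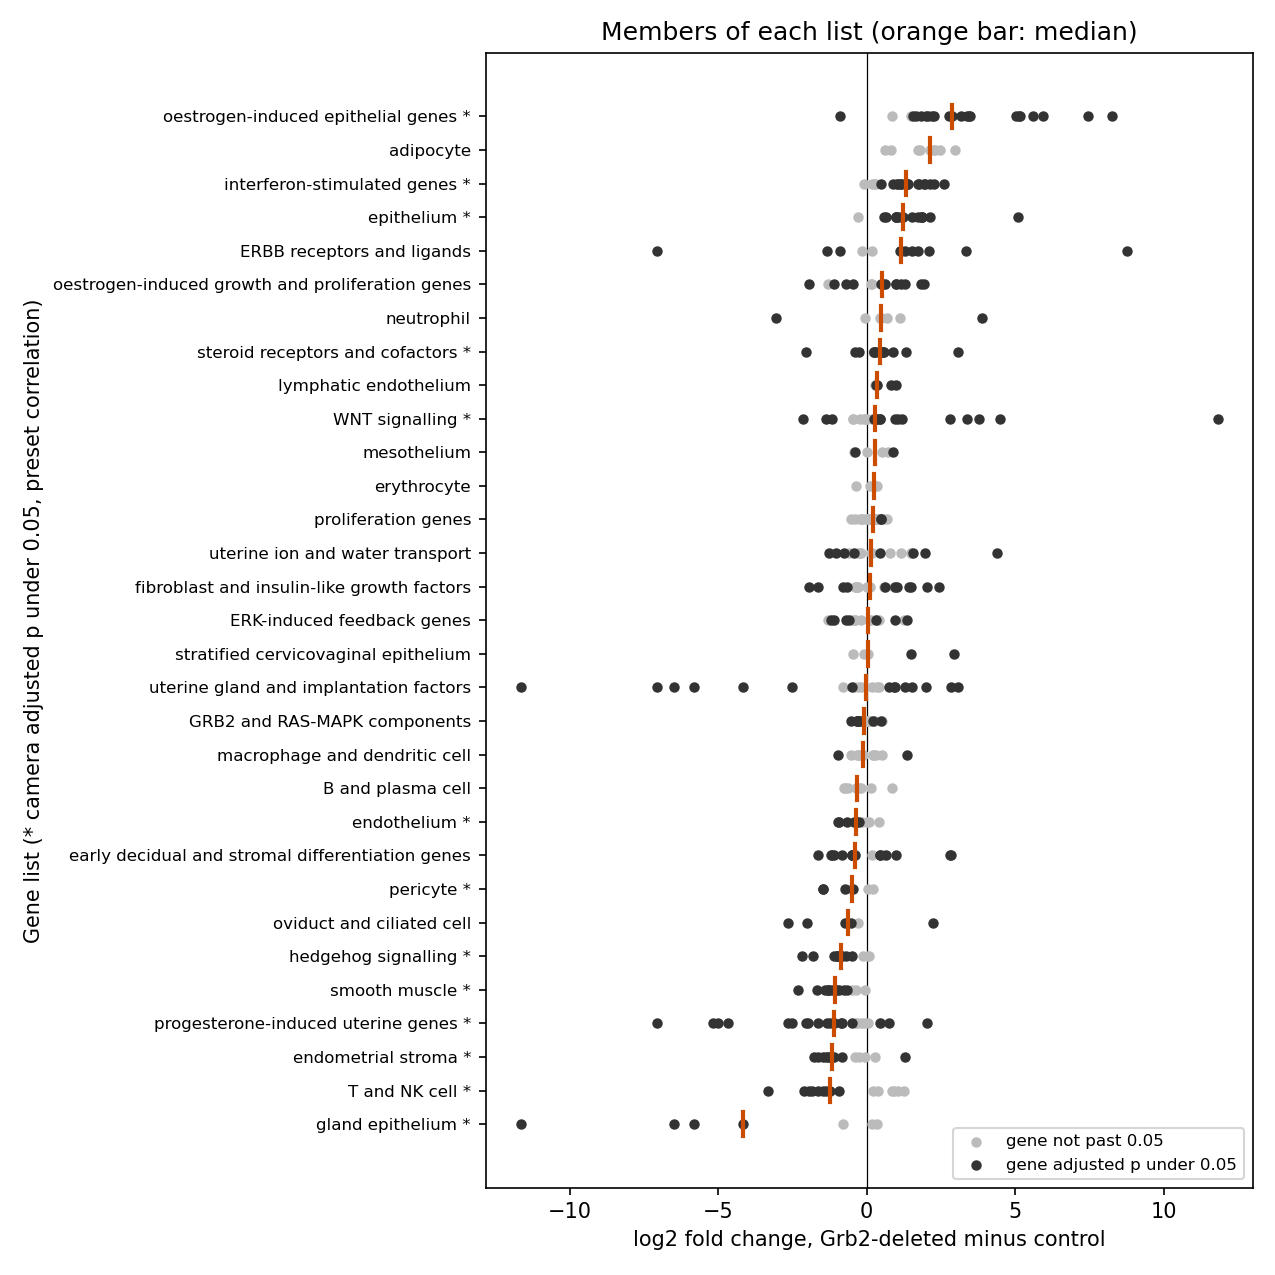
Log2 fold change (Grb2-deleted minus control) of each tested member of the 31 tested lists; dark points are genes past the threshold, orange bars list medians, asterisks lists called at the preset correlation. Medians run from -4.18 for gland epithelium to 2.86 for oestrogen-induced epithelial genes.

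Of the 31 lists tested, 13 were called at the preset correlation, 1 with an estimated correlation and 23 with fry, which asks whether members move one way without comparing them with other genes. All 13 kept their direction and their call in each fit that left out 1 library.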

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

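The tests of scaling, of cell shares, of the hedgehog list and of Grb2-deleted replicate 1 were chosen after the results were seen; those of other splits and of GC content and length were set before. A bound of 90% was set for the mislabelling test before its value was known, was missed, and was replaced afterwards as described.

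No other split of the 8 libraries into 4 and 4 called any gene with edgeR: the count of 6421 was reached by 1 of 35 splits, the real one, and the highest of the others was 0 (at most 1756 genes at an unadjusted p under 0.05). The smallest share that 35 splits can give is 1 of 35. Each of the others also mixes the genotypes, so a real difference widens the spread within its groups. These splits therefore cannot exclude chance.

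Epithelial markers were higher and stromal markers lower by list medians of 1.22 and -1.16. Library scaling cannot make the difference between the list medians, 2.38, since a factor shared by all genes leaves it unchanged. Nor did GC content and transcript length, whose joint trend spanned 0.36 over all tested genes (percentiles 1 to 99) and left a difference of 2.35 once removed. Changed cell shares cannot be told apart from an effect of the genotype within cells. Members of a list moved by unequal amounts (I2 of 97% for epithelium and 95% for stroma), but markers also differ in their level in other cells, and a changed share of gland against luminal epithelium may add to this.

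Hedgehog genes were lower with a median of -0.85. A lower share of stromal cells was not excluded. Hedgehog genes outside the stroma list lay 0.27 above the stroma markers in median log2 fold change (two-sided permutation test over genes, p = 0.353). No larger fall of the list as a whole was detected. The genes compared include the ligand gene Ihh and are not limited to targets of the signal, so a larger fall of targets stays open. Ptch2, at -2.19, fell past the lowest stroma marker, at -1.77, but is 1 member of 13. A fall of Ihh as large as that of the list was outside the 95% interval of Ihh, -0.73 to 0.82, but narrowly, and a smaller fall or a change in the protein stays open. That interval is for whole uterus. Epithelium markers rose by a median of 1.22 in the same libraries, so a lower Ihh level per epithelial cell stays open too. Reduced signalling in stroma and fewer stromal cells were not separated.

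Grb2-deleted replicate 1 stood apart, with proliferation genes lower than in the other 3 deleted libraries by a median log2 difference of -2.23. Its depth of 41.4 M counts lay within the range of the others, 37.9 to 41.7 M. Of genes called at 2-fold without it, 84.7% were nearer in it to the deleted than to the control mean, short of the bound of 90% but far above the 3.0% to 9.4% for controls held out in turn (90.5% to 93.9% for the other deleted libraries), so a mislabelled control is unlikely. Fewer leukocytes cannot be told apart from a change in proliferating cells, since leukocyte lists fell by both more and less than proliferation genes: -3.00 for B and plasma cell, -2.25 for neutrophil, -1.38 for macrophage and -0.69 for T and NK cell markers. A difference in stage or physiology between samples may also contribute and was not tested.

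In 20 of 308 groups of 4 libraries checked, 1 library lay far from the other 3 by Dixon's ratio (gap over range), and chance alone gives about 1 in 20. In controls these were replicate 1 for Grb2 (0.83, low), Wif1 (1, high), Foxi3 (1, high) and Cyp3a59 (0.843, high), replicate 3 for Rims3 (0.835), Gjb2 (0.861), Spred2 (0.888) and the ovary list (0.9), each low, and replicate 4 for Notch3 (0.94, low). Wif1 and Foxi3 had a single count there. In deleted libraries, replicate 1 was low for Mcm2 (0.944), the oestrogen-induced growth list (0.896), the GRB2 and RAS-MAPK list (0.843) and the T and NK cell list (0.845), and high for Dnah5 (0.853) and Prss29 (1, from 2 counts). Replicate 2 was low for Cd163 (0.924) and the mesothelium list (0.913) and high for Ly6g (0.891). Replicate 3 was high for Scnn1b (0.893), and replicate 4 was low for Dusp4 (0.896).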

How the results depend on the processing

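The list member counts without 1 library and by tool and the list tests with an estimated correlation without 1 library, given with the lists in the results, were chosen after the results were seen. So were the family tests with an estimated correlation, the comparison of folds and errors with the smooth muscle covariate and the use of list medians for direction. The other alternatives were fixed before.

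Of genes called both with the reported settings and with an alternative, 0 changed sign. Other scalings, filters, the replicate block, non-robust moderation, DESeq2 and limma-voom called 5807 to 7204 genes. Leaving out 1 library gave 4983 to 7138 genes, 2465 to 3524 risen and 2504 to 3614 fallen, 2145 to 2443 at least 2-fold, a Grb2 log2 fold change of -0.372 to -0.266, and 13 to 16 lists. Beside the counts given with the lists, leaving out 1 library moved these by over 1.5 times: ion and water transport from 4 to 2 risen (control replicate 2 or Grb2-deleted replicate 4), endothelium from 0 to 1 risen (control replicate 1 or Grb2-deleted replicate 2), stroma from 1 to 2 risen (control replicate 3) and oviduct from 4 to 1 or 2 fallen (control replicate 4, Grb2-deleted replicate 2 or 4). With an estimated correlation, leaving out Grb2-deleted replicate 2 also brought a call of the progesterone-induced list (adjusted p = 0.00637). The smooth muscle covariate, 79.2% of whose variance followed genotype, left 1100 genes, 722 risen, 378 fallen and 918 at least 2-fold, with Grb2 at -0.452 (adjusted p = 0.18; 0.0018 to 0.05 under the other alternatives). It raised the SE by a median of 2.17 times over all tested genes. Of 49 named genes whose call it ended, Grb2 included, 12 had a larger log2 fold change with it. In 17 the log2 fold change was smaller by over 1.5 times, so most of these lost calls went with wider errors. Among the 17 were Tdo2 (-2.02, against -5.65) and Dnah5 (-0.12, against -2). The covariate also ended the calls of the steroid receptor list (adjusted p = 0.0607) and, by construction, of the smooth muscle list. Still 13 lists were called with it, as in the reported fit, so other lists gained a call. Among these was the proliferation list, called downward. Lists called were 1 with an estimated correlation and 23 with fry. Replicate numbers did not pair the libraries: correlations of same-numbered deviations were 0.031, -0.096, 0.028 and 0.041, and no library matched its own number best. With the replicate block 5807 genes were called.

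By the direction of the test, 24 of 463 list tests differed from the reported one, 0 of them for a called list. Lists and genes without a call in the reported fit changed the sign of their value as follows. The cause was not tested. The smooth muscle covariate gave proliferation -2.03 (adjusted p = 1.46e-05), neutrophil -1.16, adipocyte -0.99 and Cfd -0.988. Gland and implantation was at 0 (upper quartile), 0.09 (library size) and 0.18 (strict filter), and GRB2 and RAS-MAPK at 0.01 (library size). ERK feedback was at -0.06 with no filter, ion and water transport at -0.01 with the strict filter, and proliferation at -0.06 with the block. Ranges over fits without 1 library were -0.2 to 0.1 for gland and implantation, -0.41 to 0.08 for macrophage, -0.12 to 0.57 for mesothelium, -0.03 to 0.76 for stratified epithelium, -0.02 to 0.14 for ERK feedback, -0.08 to 0.32 for ion and water transport, -0.83 to 0.02 for B and plasma cell, -0.16 to 0.53 for proliferation, -0.12 to 0.71 for erythrocyte, -0.199 to 0.343 for Star, -0.082 to 0.705 for Hbb-bs and -0.148 to 0.491 for Hba-a1. With no filter, 17 lists were called, the added ones being gland and implantation, decidual, lymphatic and adipocyte; with the block 15, adding ERBB and decidual. In the simulation, changes of 0.5 in log2 were recovered in 46.7% of the changed genes. It changed far fewer genes than were called here and took its spread from controls alone. That share therefore does not measure the sensitivity in these data, where small changes may still be missed.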

Other observations

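All gene families and tests in this part were chosen after the data were seen, including the test of genes near Pgr.

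Families defined by a shared symbol stem with at least 10 tested protein-coding members numbered 183, and 8 were called with camera at the preset correlation. With an estimated correlation 0 were called (adjusted p = 0.986 for each of the 8 with camera), so each is a description of these libraries. Genes with the stem Col, collagens apart from Col4a3bp (a ceramide transfer protein gene, fallen), had 23 of 41 members fallen and 6 risen (median log2 fold change -1.16, adjusted p = 3.07e-08); 5 of the 41 are on the stroma list, which fell by the same median. Of the extracellular ADAMTS proteases, 14 of 18 fell and 1 rose (median -1.12, adjusted p = 1.83e-05). The largest fall was in Adamts16, from 21.6 to 2.44 CPM, and Adamts6 rose. Keratins (Krt) had 9 of 16 risen and 0 fallen (median 1.34), with Krt17 at 0.342 and 4.84 CPM and Krt80 at 3.30 and 14.2 CPM. The epithelium list, which rose, holds 4 of these keratins and 3 of the claudins. Claudins (Cldn), which form tight junctions, had 7 of 16 risen and 0 fallen (median 0.56, adjusted p = 0.0386); Cldn1 rose from 28.9 to 100.5 CPM and Cldn2 from 0.942 to 5.93 CPM. WNT ligand genes (Wnt) had 5 of 11 risen and 1 fallen (median 0.48, adjusted p = 0.0156), and share members with the WNT list. Septins had 6 of 11 fallen and 0 risen, and FKBP family members 7 of 13 fallen and 1 risen. Among the latter were Fkbp10, Fkbp11 and Fkbp14, of the endoplasmic reticulum, where collagen is folded. Ribosomal protein genes of the large subunit (Rpl) had 22 of 47 fallen and 0 risen, with a small median of -0.22. The Rpl median was -0.12 with library size alone, a scaling that itself moved all genes by about 0.1.

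Genes near Pgr were examined because the deleted animals alone carried the Cre allele, and DNA flanking an engineered allele can differ in strain from the other chromosome. Within 10 Mb of Pgr, 27 of 65 tested genes (41.5%) were called, against 36% elsewhere. The odds ratio was 1.26 (upper 95% bound 2.13, Fisher's exact test, two-sided, p = 0.366). A modest effect of flanking DNA may exist within that bound and was not resolved. Called changes of at least 2-fold made up 12.3% of genes there and 12.9% elsewhere (odds ratio 0.95, Fisher's exact test, two-sided, p = 1). Of these 8 genes 5 were higher, among them the matrix metalloproteinase genes Mmp7, Mmp10 and Mmp12 (log2 fold changes 5.76, 5.26 and 2.83), and Gria4, Gpr83 and Naalad2 were lower. The nearest of them to Pgr was Arhgap42, which starts at 8994329, while Pgr ends at 8968611. Arhgap42 rose from 63.2 to 156.2 CPM (log2 fold change 1.31, adjusted p = 0.000244, edgeR). Pgr itself, left out of these counts, also rose. A local effect of the Cre allele on Arhgap42 was not tested. The Mmp family as a whole had 5 of 15 members risen and 5 fallen.

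Several transcripts split the libraries of 1 group into 2 and 2. The predicted gene Gm8730 was at 89.3 and 88.7 CPM in control replicates 3 and 4, 4.83 and 4.98 CPM in control replicates 1 and 2, and 3.22 to 3.71 CPM in all deleted libraries. Gm14165 and Gm9625 had the same split, at 16.4 and 16.6 against 0.394 and 0.425 CPM and at 43.5 and 47.1 against 4.26 and 4.15 CPM. Rps3a3 was at 2.67 to 2.91 CPM in control replicate 1 and in Grb2-deleted replicates 1 and 3, and at 116 to 154 CPM in the remaining libraries.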
